A study of Sus scrofa domesticus with 28 samples.

How the data were processed

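Gene expression was measured on 28 Agilent pig arrays, 1 per biopsy, on 7 slides of 4 arrays. Per the labels, biopsy RNA was labelled with Cy5 and a universal pig reference RNA with Cy3 on every array, without dye swap, and the biopsies came from 2 juvenile male red Duroc pigs, numbered 49 and 50. Per the file headers, Agilent Feature Extraction 10.7.1.1 read each scan and gave the median brightness of each spot and of its local background as intensity on a linear scale. The same deposited scanner files hold the signals that the program had background-subtracted and dye-normalised, also as intensity, and their ratio of Cy5 to Cy3 on a log10 scale. The authors also deposited a value table in log2 units. Its values equalled the log2 ratio of the scanner's processed signals within 0.001 for 99.97 to 99.99% of probes on each array, and further steps were not stated.

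The median spot intensities were used. Backgrounds were subtracted with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, and the log2 ratios were normalised by loess within each array. Before this step each local background was capped at the 99th percentile of its array and channel. This was a departure from the plan, made after the data were seen: a few spots had local backgrounds of up to 649958, and without the cap the corrected Cy5 signal of the negative controls was above 100 on 14 of 28 arrays and reached 2327, against 67.1 to 74.9 with it. The uncapped values are given as an alternative. Spots flagged as outliers by the scanner program were treated as missing.

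A probe was kept where its Cy5 signal was well above background, by the scanner program's own flag, on at least 4 arrays, which left 24513 of 43603 probes. A gene symbol was assigned by matching the probe's accession to RefSeq transcripts, which gave one for 6924 probes of 3216 genes. The others were identified by their transcript accession alone. Where a gene or accession had several probes, the probe with the highest mean Cy5 signal stood for it. This gave 18768 features, 2646 with a symbol and 16122 without, and 5 were left out because all values of a group were flagged. Of the feature values 0.53% were missing, in 2366 features. The number of arrays limits the precision. Cy5 signal was well above background on 31.4 to 55.7% of probes per array. Where a gene was well above background on 0 arrays of a group, a bound is given from the Cy5 channel as "at least" a fold against the lowest well-above-background signal. That channel is on another scale than the ratio to the reference, so the bound can exceed the fitted difference.

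A single linear model was fitted with limma to the 28 arrays, with 11 group means and the animal as a block. From it came 13 comparisons: scar at each phase against control skin, late against early sham scar, hyper against hypo scar over all phases and at each phase, the change of that difference between early and late scar, hyper and hypo scar against control skin, pressure against sham scar, and the difference of the pressure effect between hyper and hypo scar. P values were adjusted by Benjamini-Hochberg over the features of each comparison, with a threshold of 0.05. The number in the sample titles that differs between phases has no stated unit and was not used. Pairs of a hyper and a hypo biopsy of the same animal, side and phase were compared for the pigment genes with an exact two-sided sign-flip permutation test. The labels name no scar site, and within 5 of the 12 pairs that number differs, so the 2 biopsies of a pair need not come from 1 scar. Another code in the titles, meaning not stated, was the same in all hyper biopsies and different from that of all hypo biopsies. Pigmentation and whatever this code marks cannot be told apart.

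Before the data were examined 29 gene lists were fixed for cell types and processes of skin and scar. The 19 lists with at least 5 measured genes were tested against the other named genes with camera (preset correlation 0.01, and again with the correlation estimated for each list), adjusted over the lists of each comparison. The lists for Schwann cells, collagen processing, basal and differentiated keratinocytes, hair follicle, sweat gland, B and plasma cells, mast cells, red blood cells and the WNT pathway had 0 to 4 measured genes and were not tested. Of 247 tests of a list in a comparison 83 passed with the preset correlation and 2 with the estimated one. In each test that passed, the list's median, mean and test had the same sign. They differed in sign for some lists that did not pass. The named genes were chosen by a rule fixed before the data were examined. They are up to 8 highest and 8 lowest called genes with a symbol and the same sign in both animals, up to 4 members of lowest p of each list described, the pigment genes in comparisons of hyper and hypo scar, and, where fewer than 4 genes passed, up to 10 of lowest p. Not every gene that the rule selects is described.

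Alternatives fixed before the data were seen were the scanner program's own ratio, the deposited value table, a further normalisation between arrays, the Cy5 channel alone, no filter or a filter of 14 arrays, no animal term, slide as a random block (correlation 0.0625), the pair of animal, side and phase as a block, the mean of all probes, each animal alone, sham or left-side biopsies alone, the early right minus left difference subtracted, and leaving out each array in turn. After the data were seen, 5 were added: backgrounds not capped, the share of probes with Cy5 signal well above background as a covariate, leaving out 4 biopsies with a muscle signal, leaving out the 2 dimmest arrays, and slide as a fixed block. Slides that held both compared groups also gave within-slide differences. On simulated data with the spread of these arrays and 200 changed features, 2-fold changes were recovered in 73.1 to 95.5% of cases for the comparisons of groups and in 31.3 and 37.3% for the differences of differences. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.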

Results

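The data are 28 skin biopsies of 2 red Duroc pigs, a breed that forms thick, raised scars after deep skin wounds. Each biopsy was compared with a universal pig reference RNA on its own Agilent array. The biopsies comprised 4 of control skin, 4 of early hyperpigmented scar and 4 of early hypopigmented scar. A further 2 biopsies came from each of 8 scar groups, formed by phase (mid or late), treatment (sham or pressure) and pigmentation (hyper or hypo). Cy5 signal, which carries the biopsy, was well above background on 13709 to 24300 of 43603 probes per array (median 20325, 46.6%). Differences below are log2 differences ± SE of the biopsy-to-reference ratio with Benjamini-Hochberg adjusted p from limma, over 18768 tested features. With 2 animals, p measures the spread between biopsies of these animals and not between pigs.

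The first comparisons asked how scar differed from control skin at each phase. In early scar, genes of the collagen matrix were many times higher than in control skin, and genes of lipid synthesis and some pigment genes were lower. Among the strongest rises were the small collagen-binding proteoglycan ASPN (4.55 ± 0.51, adjusted p = 1.54e-06), the large proteoglycan VCAN (3.21 ± 0.41, adjusted p = 6.13e-06), and the matricellular protein POSTN (3.11 ± 0.44, adjusted p = 1.92e-05). So were the collagen chains COL5A2 (3.38 ± 0.46, adjusted p = 1.38e-05) and COL1A2 (3.37 ± 0.66, adjusted p = 4.60e-04). C1QTNF3 (4.79 ± 0.71), the growth factor pleiotrophin PTN (3.78 ± 0.59) and PHACTR3 (3.67 ± 0.55) also rose, with adjusted p from 2.99e-05 to 5.43e-05. Of the fixed list of fibrillar collagens and matrix genes, 11 of 12 measured members rose (11 adjusted over the list alone). The median of the list was 2.88 (camera adjusted p = 1.27e-06, estimated-correlation adjusted p = 0.233). On the 2 slides that held both groups the median of this list was 2.93 to 4.07. In all, 7286 features passed the threshold in 8 early scar against 4 control arrays, 4516 higher and 2770 lower. Of them 1970 differed at least 2-fold. Of these features 1035 carry a gene symbol, and the median of all tested features was 0.11.

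Matrix remodelling and signalling genes rose with the collagens. Of the proteases and inhibitors of the matrix, 8 of 12 rose (10 adjusted over the list alone), with median 1.66 (camera adjusted p = 1.05e-04, estimated-correlation adjusted p = 0.233). Among them were the membrane protease MMP14 (3.56 ± 0.41, adjusted p = 2.86e-06) and MMP11 (2.85 ± 0.36, adjusted p = 6.43e-06). The protease inhibitors TIMP2 (2.04 ± 0.26, adjusted p = 6.09e-06) and TIMP1 (1.85 ± 0.29, adjusted p = 7.62e-05) rose as well. Of the TGF-beta pathway list 6 of 12 rose and 1 fell, 7 and 1 adjusted over the list alone. Its median was 0.45 (camera adjusted p = 0.0408, estimated-correlation adjusted p = 0.412). Its members include the ligands TGFB3 (2.0 ± 0.32) and TGFB1 (1.33 ± 0.23), the secreted factor CTGF (2.58 ± 0.46) and the co-receptor ENG (1.08 ± 0.23), with adjusted p from 7.29e-05 to 0.0010. Endothelial genes rose in 6 of 9 cases (7 adjusted over the list alone, median 0.90, camera adjusted p = 0.0103, estimated-correlation adjusted p = 0.425). They were led by the vessel growth factor ANGPT2 (1.42 ± 0.21, adjusted p = 2.42e-05) and the clotting factor VWF (1.33 ± 0.24, adjusted p = 1.79e-04).

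Lipid synthesis genes fell as a list in early scar, and some single genes of glands and hair fell too. The apocrine pheromone-binding protein subunit PHEROC (-7.01 ± 0.73, adjusted p = 6.54e-07) and the secretoglobin SCGB1D1 (-6.13 ± 0.73, adjusted p = 3.23e-06) fell most clearly, with the hair keratin KRT31 (-4.15 ± 0.13, adjusted p = 5.70e-15) and relaxin RLN2 (-3.52 ± 0.17, adjusted p = 1.22e-11). KRT31 was well above background on 0 of 8 early scar and 4 of 4 control arrays. In the Cy5 channel it was at least 85.9-fold lower. DAPL1 (-5.01 ± 0.55), PLET1 (-4.08 ± 0.42), FAM84A (-3.99 ± 0.50) and MAL2 (-3.71 ± 0.45) fell too, with adjusted p from 5.64e-07 to 5.31e-06. Of the sebaceous gland and lipid synthesis list 10 of 13 fell (10 adjusted over the list alone). They include stearoyl-CoA desaturase SCD (-3.33 ± 0.19, adjusted p = 2.96e-10) and the lipid droplet coat protein PLIN2 (-1.47 ± 0.20, adjusted p = 1.59e-05). The list had a median of -1.38 (camera adjusted p = 8.89e-05, estimated-correlation adjusted p = 0.0511). Of the adipocyte list 7 of 13 fell (7 adjusted over the list alone, camera adjusted p = 0.0156, estimated-correlation adjusted p = 0.555), which with slide as a fixed block did not pass (camera adjusted p = 0.0791). Examples are the lipases PNPLA2 (-1.17 ± 0.19) and LIPE (-2.23 ± 0.52, with 2 of 3 probes in this direction), the droplet coat PLIN1 (-1.06 ± 0.21) and the fatty acid carrier FABP4 (-3.07 ± 0.70). PLIN1 was well above background on 0 of 8 early scar and 4 of 4 control arrays, in the Cy5 channel at least 2.04-fold lower.

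Of 14 pigment genes 6 were lower and 1 higher in early scar than in control skin. Tyrosinase TYR (-2.86 ± 0.20, adjusted p = 5.36e-09), the first enzyme of melanin synthesis, and TYRP1 (-1.59 ± 0.28, adjusted p = 1.52e-04), a later enzyme of the same pathway, both fell. The melanosome transport genes RAB27A (-0.95 ± 0.15, adjusted p = 5.45e-05) and MLPH (-0.71 ± 0.15, adjusted p = 7.02e-04) fell too. RAB27A was well above background on 0 of 8 early scar and 4 of 4 control arrays, in the Cy5 channel at least 1.86-fold lower. Of the melanocyte and pigment list 6 of 14 fell and 1 rose, 7 and 1 adjusted over the list alone (median -0.54, camera adjusted p = 0.0156, estimated-correlation adjusted p = 0.233). Of the list of signals acting on melanocytes 3 of 6 fell (4 adjusted over the list alone, camera adjusted p = 0.0246, estimated-correlation adjusted p = 0.189). It did not pass with slide as a fixed block (camera adjusted p = 0.0695). Among them were BMP4 (-1.37 ± 0.15), IL1A (-0.74 ± 0.13) and AGRP (-0.36 ± 0.13), with adjusted p from 1.54e-06 to 0.0291. BMP4 was well above background on 0 of 8 early scar and 4 of 4 control arrays, in the Cy5 channel at least 2.4-fold lower. The AGRP call was lost in 4 of 12 fits that left out 1 array (adjusted p there from 0.0554 to 0.153).

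Immune genes rose in part. Of the macrophage and dendritic cell list 9 of 18 rose (9 adjusted over the list alone, camera adjusted p = 0.0156, estimated-correlation adjusted p = 0.624). Among them were the class II gene SLA-DQA1 (1.36 ± 0.30), the complement chains C1QA (0.85 ± 0.20) and C1QB (1.39 ± 0.36) and the scavenger receptor CD163 (1.89 ± 0.47). Of the interferon response list 6 of 15 rose (6 adjusted over the list alone, camera adjusted p = 0.0156, estimated-correlation adjusted p = 0.555), among them IRF9 (0.57 ± 0.13) and OAS2 (1.01 ± 0.23, with 4 of 5 probes in this direction). The other 9 lists missed the threshold in early scar, with camera adjusted p = 0.105 for skeletal muscle, 0.164 for cell cycle, 0.212 for inflammatory cytokines and chemokines and 0.388 for T and NK cells. It was 0.608 for retinoid, steroid and stress hormone genes, 0.665 for myofibroblast and smooth muscle genes, 0.665 for activated keratinocytes, 0.745 for neutrophils and 0.985 for immediate early and heat shock genes. The direction was the same within each of the 2 slides holding early scar and control skin for 98.6 to 99.9% of the features past the threshold. The arrays of these slides are among those that gave the calls, here and below, so agreement is in part built in. Animal 50 alone gave 2830.

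**Figure D1:**
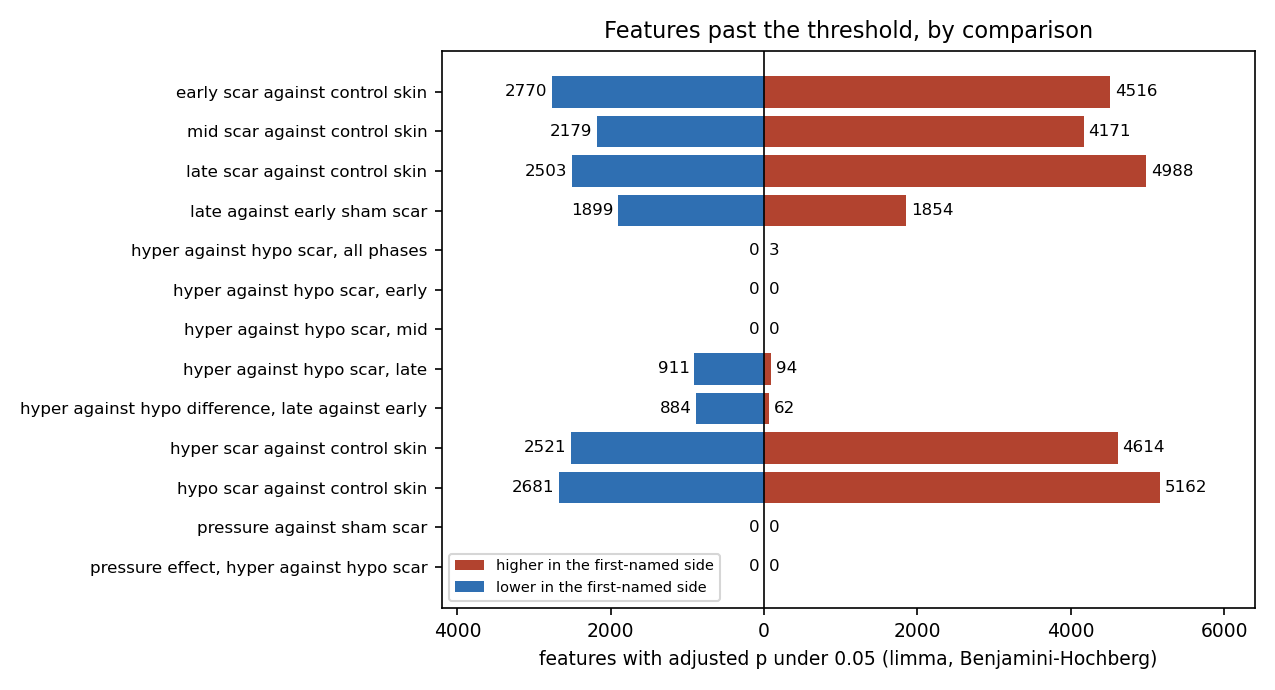
Number of features past the threshold (limma, adjusted p below 0.05) in each comparison, higher in the first-named group and lower in it. Early, mid and late scar against control skin gave 7286, 6350 and 7491, and hyper against hypo scar gave 3 over all phases.

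Mid scar was set against the same 4 control arrays. The matrix genes ASPN (3.04 ± 0.51, adjusted p = 2.33e-04), VCAN (2.14 ± 0.41, adjusted p = 6.26e-04), COL5A1 (2.17 ± 0.42, adjusted p = 7.15e-04) and LUM (1.29 ± 0.31, adjusted p = 0.0039) rose, as did the retinoic acid binding protein CRABP1 (2.18 ± 0.46, adjusted p = 0.0014). Of the matrix list 6 of 12 rose (9 adjusted over the list alone), with median 1.45, camera adjusted p = 4.40e-04, estimated-correlation adjusted p = 0.43. C1QTNF3 (2.49 ± 0.71), PTN (2.08 ± 0.59), COL8A1 (2.08 ± 0.55) and the phagocyte oxidase subunit GP91-PHOX (1.98 ± 0.73) rose with adjusted p from 0.0070 to 0.0424. The GP91-PHOX call was lost in 7 of 12 fits that left out 1 array (adjusted p there from 0.0723 to 0.117). Without control replicate 50L C1QTNF3 (1.94, adjusted p = 0.0741) and COL8A1 (1.59, adjusted p = 0.0553) missed the threshold. PHEROC (-6.88 ± 0.73), SCGB1D1 (-6.11 ± 0.73), PLET1 (-4.30 ± 0.42), LY6G6D (-4.01 ± 0.50), DAPL1 (-3.61 ± 0.55) and the carbonic anhydrase CA6 (-3.34 ± 0.22) fell, with adjusted p from 1.48e-09 to 8.59e-05. KRT31 (-4.13 ± 0.13) and RLN2 (-3.75 ± 0.17) were well above background on 0 of 8 mid scar and 4 of 4 control arrays. In the Cy5 channel they were at least 86.5-fold and 15.7-fold lower, with adjusted p from 6.17e-15 to 4.82e-12.

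In mid scar, 7 of 12 proteases and inhibitors of the matrix rose (8 adjusted over the list alone, camera adjusted p = 0.0024, estimated-correlation adjusted p = 0.41). Among them were MMP14 (1.98 ± 0.41, adjusted p = 0.0014) and TIMP1 (1.35 ± 0.29, adjusted p = 0.0016). Endothelial genes rose in 7 of 9 cases (8 adjusted over the list alone, camera adjusted p = 3.83e-04, estimated-correlation adjusted p = 0.303). They include ANGPT2 (1.52 ± 0.21, adjusted p = 2.90e-05) and the junction gene CDH5 (1.47 ± 0.29, adjusted p = 9.00e-04). Macrophage and dendritic cell genes rose in 8 of 18 cases (11 adjusted over the list alone, camera adjusted p = 0.0018, estimated-correlation adjusted p = 0.487). They include the class II genes SLA-DQA1 (1.49 ± 0.30) and SLA-DRA (1.23 ± 0.31), with adjusted p from 0.0010 to 0.0053. The mean of this list was 1.38 in 49L of mid sham hypo and 1.29 in 50R of mid pressure hyper scar, and at most 0.09 in the other 6. Interferon response genes rose in 6 of 15 cases (7 adjusted over the list alone, camera adjusted p = 8.52e-04, estimated-correlation adjusted p = 0.41). Sebaceous and lipid synthesis genes fell in 9 of 13 cases (9 adjusted over the list alone, camera adjusted p = 1.93e-04, estimated-correlation adjusted p = 0.0526), with SCD (-3.03 ± 0.19, adjusted p = 1.34e-09) and SQLE (-1.53 ± 0.23, adjusted p = 9.20e-05). Adipocyte genes fell in 6 of 13 cases (6 adjusted over the list alone, camera adjusted p = 0.0439, estimated-correlation adjusted p = 0.529), not past the threshold with slide as a fixed block (camera adjusted p = 0.185). Pigment genes fell in 6 of 14 cases (7 adjusted over the list alone, camera adjusted p = 0.0128, estimated-correlation adjusted p = 0.303). Those that fell include TYR (-3.01 ± 0.20, adjusted p = 2.59e-09), TYRP1 (-1.80 ± 0.28, adjusted p = 9.69e-05) and the endothelin receptor EDNRB (-0.85 ± 0.21, adjusted p = 0.0050). Signals acting on melanocytes fell in 3 of 6 cases (3 adjusted over the list alone, camera adjusted p = 0.0189, estimated-correlation adjusted p = 0.156).

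Skeletal muscle genes rose in 2 of 24 cases in mid scar (2 adjusted over the list alone, median 1.11, camera adjusted p = 0.0128, estimated-correlation adjusted p = 0.602). The muscle list stood 4.01 log2 units above the median of all arrays in the 49R biopsy of mid pressure hyper scar, and at most 0.92 above it in the other mid biopsies. In all 6350 features passed, 4171 higher and 2179 lower, against 8311 at an unadjusted p under 0.05. Within 2 slides 93.5 to 97.6% of them had the same direction. Of them 3879 were shared with the 3899 that passed without control replicate 50L.

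Late scar differed from control skin in matrix, lipid and pigment genes, and the interferon response was higher in nearly the whole list. Of 15 interferon response genes 13 rose (14 adjusted over the list alone, median 0.88, camera adjusted p = 2.71e-05, estimated-correlation adjusted p = 0.293). Examples are the transcription factor IRF9 (0.74 ± 0.13, adjusted p = 1.48e-04) and the antiviral genes IFIT1 (1.15 ± 0.20, adjusted p = 1.67e-04) and OAS2 (1.30 ± 0.23, adjusted p = 2.17e-04). Of the T and NK cell list 5 of 14 rose (9 adjusted over the list alone, camera adjusted p = 0.0134, estimated-correlation adjusted p = 0.395). Among them were the cytotoxic protease GZMB (0.98 ± 0.19, adjusted p = 4.17e-04), the receptor KLRK1 (0.67 ± 0.16, adjusted p = 0.0024) and the T cell receptor chain CD3G (0.62 ± 0.17, adjusted p = 0.0069). Of the cytokine and chemokine list 5 of 22 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0386, estimated-correlation adjusted p = 0.395). Here CCL19 (1.57 ± 0.31), CCL2 (1.68 ± 0.40) and IL6 (1.13 ± 0.27) were higher and IL1A (-0.70 ± 0.13) lower. With slide as a fixed block neither the T and NK cell nor the cytokine list passed (camera adjusted p = 0.0868 and 0.0579). Cell cycle genes fell in 5 of 9 cases (camera adjusted p = 0.010, estimated-correlation adjusted p = 0.395). Adjusted over the list alone 5 fell and 1 rose. Among them were the topoisomerase TOP2A (-1.38 ± 0.19, adjusted p = 1.46e-05), the replication factor MCM3 (-0.76 ± 0.16, adjusted p = 0.0011) and the cyclin CCNB1 (-1.0 ± 0.26, adjusted p = 0.0046).

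The WNT antagonist SFRP4 (2.44 ± 0.53, adjusted p = 0.0011) and the matrix genes ASPN (2.24 ± 0.51, adjusted p = 0.0018), POSTN (2.0 ± 0.44, adjusted p = 0.0014) and COL5A1 (1.76 ± 0.42, adjusted p = 0.0024) rose in late scar. In all 7 of 12 matrix genes rose (7 adjusted over the list alone, camera adjusted p = 0.0052, estimated-correlation adjusted p = 0.49). Leucocyte genes with large rises were the chemokine receptor CCR1 (2.39 ± 0.85), the integrin chain ITGB2 (2.08 ± 0.66), GP91-PHOX (2.03 ± 0.73) and the complement receptor C5AR1 (2.03 ± 0.70), adjusted p from 0.0165 to 0.0326. The CCR1 call was lost in 8 of 12 fits that left out 1 array (adjusted p there from 0.0513 to 0.0702). It was lost in 6 of 12 for GP91-PHOX (0.0576 to 0.0921) and 6 of 12 for C5AR1 (0.0507 to 0.0909). Macrophage and dendritic cell genes rose in 7 of 18 cases (camera adjusted p = 0.0052, estimated-correlation adjusted p = 0.506). Adjusted over the list alone 10 rose and 1 fell. The mean of this list stood highest in the 49L biopsies of late sham hyper (1.42) and hypo scar (0.64), and was -0.66 to 0.18 in the other 6. Endothelial genes rose in 8 of 9 cases (8 adjusted over the list alone, camera adjusted p = 6.26e-04, estimated-correlation adjusted p = 0.293). They include VWF (1.85 ± 0.24, adjusted p = 8.61e-06) and the adhesion gene PECAM1 (1.47 ± 0.29, adjusted p = 4.90e-04). Proteases and inhibitors of the matrix rose in 7 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.010, estimated-correlation adjusted p = 0.395). They include MMP14 (1.5 ± 0.43, adjusted p = 0.0093) and TIMP1 (0.99 ± 0.29, adjusted p = 0.0096). Without control replicate 50L MMP14 missed the threshold (1.26, adjusted p = 0.0521).

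PHEROC (-7.38 ± 0.73), SCGB1D1 (-6.65 ± 0.73) and RLN2 (-3.74 ± 0.17) were well above background on 0 of 8 late scar and 4 of 4 control arrays. In the Cy5 channel they were at least 232-fold, 188-fold and 15.3-fold lower, with adjusted p from 5.03e-12 to 1.93e-06. KRT31 (-3.89 ± 0.13), PLET1 (-4.31 ± 0.42), DAPL1 (-4.22 ± 0.55) and LY6G6D (-3.86 ± 0.50) fell, with adjusted p from 2.06e-14 to 1.02e-05. Sebaceous and lipid synthesis genes fell in 9 of 13 cases (9 adjusted over the list alone, camera adjusted p = 1.68e-04, estimated-correlation adjusted p = 0.0647), with SCD (-3.68 ± 0.19, adjusted p = 6.05e-11) and SQLE (-2.01 ± 0.23, adjusted p = 3.45e-06). Pigment genes fell in 6 of 14 cases (6 adjusted over the list alone, camera adjusted p = 0.0134, estimated-correlation adjusted p = 0.293), with TYR (-3.01 ± 0.20, adjusted p = 2.74e-09) and TYRP1 (-1.96 ± 0.28, adjusted p = 2.29e-05).

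Skeletal muscle genes rose in 4 of 24 cases in late scar (2 adjusted over the list alone, median 1.63, camera adjusted p = 0.0041, estimated-correlation adjusted p = 0.534). Among them was the myosin chain MYH1 (2.34 ± 0.88). The muscle-associated gene CMYA5 (2.12 ± 0.83) rose too, with adjusted p from 0.0392 to 0.0477 for both. These calls were lost in 9 of 12 fits that left out 1 array (adjusted p there from 0.0522 to 0.0903 and 0.0637 to 0.111). The muscle list stood 4.78 log2 units above the median of all arrays in the 49R biopsy of late pressure hyper scar and 1.67 above it in the 49L biopsy of late sham hyper scar. In all 7491 features passed, 4988 higher and 2503 lower. Within 3 slides 96.8 to 99.1% of them had the same direction. Cy5 signal was well above background on fewer probes in late scar (43.1% ± 3.0 in hyper and 36.6% ± 4.68 in hypo scar, SD, n = 4 each) than in control skin (48.5% ± 5.88, SD, n = 4). With that share as a covariate, an alternative chosen after the data were seen, 3359 features passed.

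**Figure D2:**
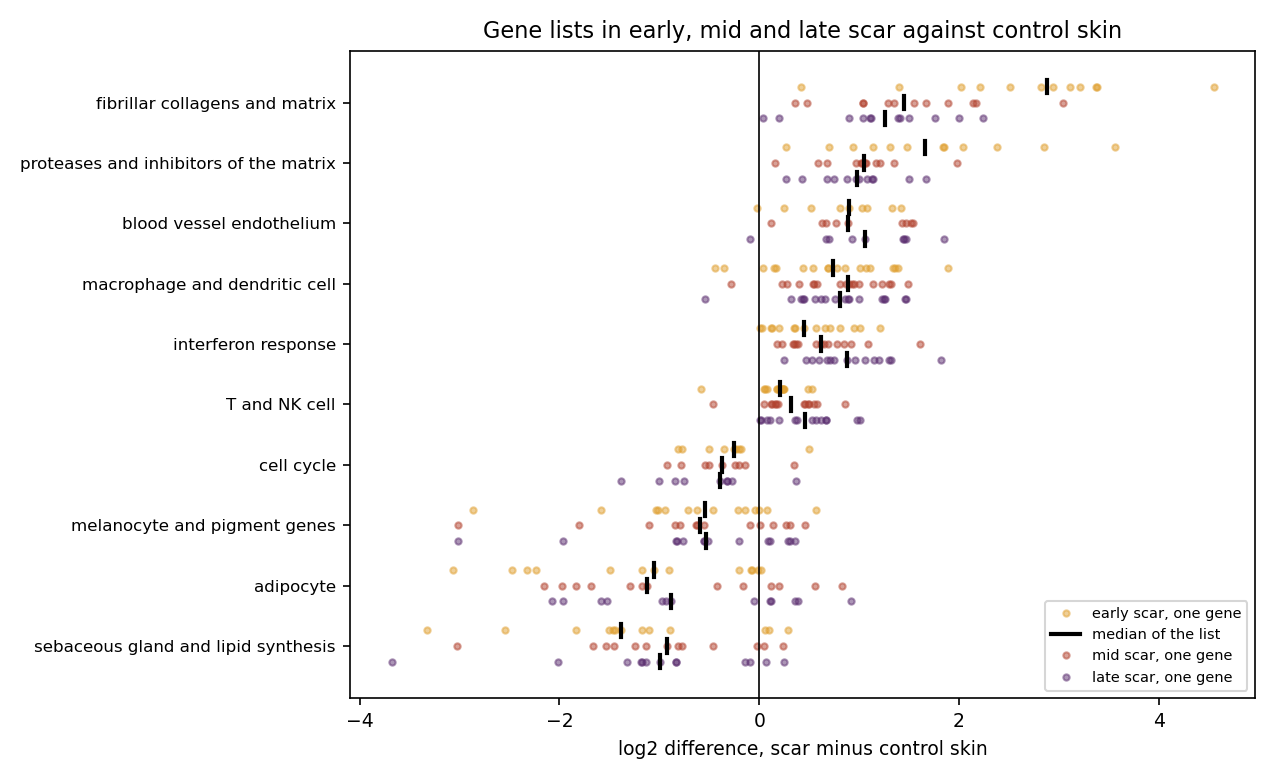
Log2 difference from control skin of each gene of 10 fixed lists in early, mid and late scar, with a bar at the median of each list. The matrix list lies highest in early scar, at 2.88, and the sebaceous and lipid synthesis list lies below 0 in all 3 phases (-1.38, -0.92 and -0.99).

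Late and early sham scar were compared directly, to ask how scar without pressure differed with time. Late sham biopsies were all from the left side and early ones from both, so side differs as well. Many matrix genes were lower and some interferon and T cell genes higher in late scar, and none of these lists passed with the estimated correlation. C1QTNF3 (-4.04 ± 0.71), PTN (-3.04 ± 0.59), PHACTR3 (-2.75 ± 0.55), ANGPTL2 (-2.62 ± 0.44) and the hyaluronan synthase SHAS2 (-2.74 ± 0.40) fell, with adjusted p from 4.21e-04 to 0.0028. ASPN (-2.44 ± 0.51), the cadherin CDH11 (-2.24 ± 0.35) and the proteoglycan ACAN (-2.23 ± 0.55) fell with adjusted p from 6.16e-04 to 0.0092. Of the matrix list 8 of 12 fell and 1 rose, 11 and 1 adjusted over the list alone (median -1.62, camera adjusted p = 9.46e-06, estimated-correlation adjusted p = 0.553). The fibrillin FBN1 (-1.57 ± 0.25, adjusted p = 6.95e-04), VCAN (-1.79 ± 0.41, adjusted p = 0.0060) and the matricellular protein TNC (-2.17 ± 0.52, adjusted p = 0.0083) were among those that fell.

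The skin chemokine CCL27 (3.09 ± 0.37, adjusted p = 1.96e-04), the metallothionein MT1A (2.04 ± 0.45, adjusted p = 0.0051) and the thyroid hormone deiodinase DIO2 (1.79 ± 0.25, adjusted p = 4.21e-04) were higher in late than in early sham scar. So were the transcription factor GATA3 (1.69 ± 0.41, adjusted p = 0.0082) and the lipid enzyme DGAT2 (1.59 ± 0.37, adjusted p = 0.0067). The interferon-induced chemokine CXCL10 (1.71 ± 0.53), RHOV (1.69 ± 0.51) and ID2 (1.58 ± 0.45) also rose, with adjusted p from 0.0185 to 0.0301. These calls were lost in 6 of 12, 3 of 12 and 2 of 12 fits that left out 1 array (adjusted p there from 0.0508 to 0.296, 0.0654 to 0.238 and 0.0729 to 0.0871). Without late sham hyper replicate 50L GATA3 missed the threshold (0.97, adjusted p = 0.0889). Interferon response genes rose in 6 of 15 cases (9 adjusted over the list alone, median 0.66, camera adjusted p = 9.46e-06, estimated-correlation adjusted p = 0.553). Examples are IFIT1 (1.56 ± 0.20, adjusted p = 3.30e-04), ISG15 (1.56 ± 0.31, adjusted p = 0.0027) and IFIH1 (1.05 ± 0.20, adjusted p = 0.0024). T and NK cell genes rose in 4 of 14 cases (5 adjusted over the list alone, camera adjusted p = 0.0085, estimated-correlation adjusted p = 0.553). Examples are CD247 (0.90 ± 0.21, adjusted p = 0.0066) and KLRK1 (0.68 ± 0.16, adjusted p = 0.0069). Without late sham hyper replicate 49L KLRK1 (0.50, adjusted p = 0.0548) and ACAN (-1.78, adjusted p = 0.0582) missed it.

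In all 3753 features differed between 4 late and 8 early sham arrays, 1854 higher and 1899 lower. There were 6735 at an unadjusted p under 0.05. A single slide held both groups, and 99.4% of the features had the same direction there. The count depended on the background step: with local backgrounds not capped, as first planned, 11 features passed. It was 264 with left-side biopsies alone, 758 with the Cy5 share as a covariate, 980 with slide as a fixed block and 1052 in animal 50 alone. Without late sham hyper replicate 50L or late sham hypo replicate 50L it was 2119 and 2312.

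Hyper and hypo scar were compared to ask which genes differ between scar labelled hyperpigmented and hypopigmented. A biopsy code in the sample titles, meaning not stated, goes with pigmentation in every scar biopsy, so the comparisons cannot separate them. Over all phases 3 features passed, and TYR is the only one with a gene symbol. Tyrosinase TYR was higher in hyper scar by 0.84 ± 0.14 (adjusted p = 0.0318, 12 against 12 arrays). It was well above background on 8 of 12 hyper and 0 of 12 hypo arrays, in the Cy5 channel at least 1.58-fold higher. TYRP1 differed by 0.96 ± 0.18, which did not pass the threshold (adjusted p = 0.181). The scanner program's ratio gave 4.16 (adjusted p = 0.0010) for TYRP1 and the deposited values 3.78 (adjusted p = 0.0024). For TYR both gave 2.42 (adjusted p = 0.0025). The size of both differences and the call of TYRP1 thus depend on the scaling. TYRP1 was well above background on 9 of 12 hyper and 0 of 12 hypo arrays, in the Cy5 channel at least 1.85-fold higher. Paired by animal, side and phase, TYR was higher in the hyper biopsy of 12 of 12 pairs (mean 0.84, exact two-sided permutation p = 4.88e-04, the smallest this test can give, adjusted over the 14 pigment genes p = 0.0068). TYRP1 was higher in 11 of 12 pairs (mean 0.96, exact p = 0.0024, adjusted p = 0.0171) and MLPH in 10 (mean 0.28, exact p = 0.0347, adjusted p = 0.121). OCA2 was higher in 10 as well (exact p = 0.0122, adjusted p = 0.0570), but it was well above background on 0 of 12 hyper and 1 of 12 hypo arrays. The other 10 pigment genes differed by -0.40 to 0.25 on average (adjusted p from 0.766 to 0.912), among them DCT (0.17), KIT (0.05), MITF (0.03), SOX10 (-0.01) and MC1R (-0.14). In 5 pairs a number in the sample titles, unit not stated, differs, and TYR was higher in 7 of the 7 others. Control skin had a TYR log2 ratio of 3.05 ± 0.47 (SD, n = 4), against 0.64 ± 0.41 in early hyper and -0.27 ± 0.27 in early hypo scar (SD, n = 4 each).

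**Figure D3:**
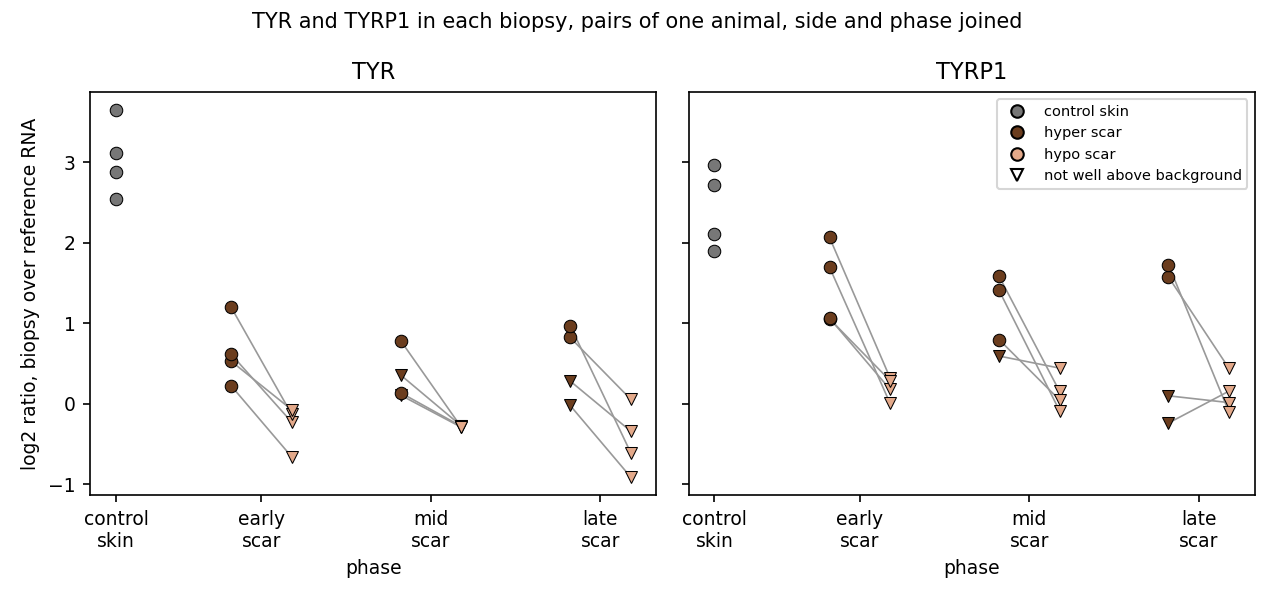
Log2 ratio to the reference of TYR and TYRP1 in each biopsy of control skin and of hyper and hypo scar at each phase, with lines joining the hyper and hypo biopsies of 1 animal, side and phase and triangles for signal not well above background. TYR averages 3.05 in control skin and lies higher in the hyper than in the hypo biopsy of 12 of 12 pairs.

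Of the 14 measured pigment genes 1 rose and 0 fell in hyper scar (3 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.0048, estimated-correlation adjusted p = 0.408). The median was above 0 on 6 of 6 slides. One member, CAPN3, stood at 2.44 and 2.16 in the 49R biopsies of mid and late pressure hyper scar, which had the highest muscle signal. It was 0.22 or lower elsewhere, and higher in the hyper biopsy of 5 of 12 pairs. Leaving out 1 array gave a median of 0.0122 (without early hyper replicate 49L) to 0.13 (without mid sham hypo replicate 50L), and the list missed the threshold without late pressure hyper replicate 50R (0.08, adjusted p = 0.0886). It also missed it with backgrounds not capped (adjusted p = 0.138), with the filter of 14 arrays (0.663) and in animal 49 alone (0.364). The 3 features that passed were all higher in hyper scar, against 459 features at an unadjusted p under 0.05, where 938 would be past it by chance in each comparison. Besides TYR these are 2 without a gene symbol, AB280952 (2.02 ± 0.24, adjusted p = 7.55e-04) and ENSSSCT00000000394 (1.67 ± 0.25, adjusted p = 0.0134). These were named after their values were seen, because the count is small. Both were well above background on 11 of 12 hyper and 1 of 12 hypo arrays. The ENSSSCT00000000394 call was lost without late sham hyper replicate 50L, late sham hypo 49L or late pressure hypo 50R (adjusted p = 0.0541, 0.0542 and 0.0505). Next in order of p came PLET1 (1.36 ± 0.28), the neuroendocrine secretory protein SCG2 (0.54 ± 0.13, in the Cy5 channel at least 1.35-fold higher, with 0 of 12 hypo arrays well above background), MYL6 (-0.34 ± 0.09), PAIP1 (0.31 ± 0.08), the epithelial adhesion gene EPCAM (0.64 ± 0.20) and the pericyte gene RGS5 (-0.54 ± 0.18). None passed the threshold, with adjusted p from 0.281 to 0.999. Endothelial genes as a list were lower (-0.22, camera adjusted p = 0.0011, estimated-correlation adjusted p = 0.583) and skeletal muscle genes higher (0.60, camera adjusted p = 0.0192, estimated-correlation adjusted p = 0.91), the latter not past the threshold with slide as a fixed block (camera adjusted p = 0.082). In limma 0 members of either passed the threshold, with a muscle signal in 3 hyper and 1 hypo biopsies. The TYR call did not hold with local backgrounds not capped (0.40, adjusted p = 1.0), where 0 features passed. Nor did it hold with slide as a fixed block (0.69, adjusted p = 1.0) or with the pair as a block (0.84, adjusted p = 0.0596), with 0 features each. The same goes for the Cy5 channel alone (0.63, adjusted p = 0.753), no animal term (0.84, 0.0856), animal 49 alone (0.67, 0.126) and animal 50 alone (1.0, 0.334). Without the muscle biopsies (0.92, 0.0711) or the 2 dimmest arrays (0.85, 0.0854) it was lost as well. It was lost in 15 of 24 fits that left out 1 array (adjusted p there from 0.0545 to 0.127).

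In early and in mid scar no feature passed between hyper and hypo scar. In early scar limma called 0 features, with 871 at an unadjusted p under 0.05. The 10 named genes of lowest p include TYRP1 (1.27 ± 0.32), TYR (0.91 ± 0.24), EPCAM (1.47 ± 0.35), GATA3 (1.68 ± 0.47), CCL27 (1.66 ± 0.43), LMO1 (1.48 ± 0.38) and the peptidase DPP4 (1.18 ± 0.30) with higher values in hyper scar and the growth factor carrier IGFBP2 (-2.02 ± 0.48) with lower values. TYR and TYRP1 were well above background on 4 of 4 early hyper and 0 of 4 early hypo arrays, in the Cy5 channel at least 1.64-fold and 2.22-fold higher. As lists, macrophage and dendritic cell genes were lower in early hyper scar (-0.70, camera adjusted p = 3.50e-08, estimated-correlation adjusted p = 0.465). The mean of this list was 0.97 and 0.63 in the 50L and 49R biopsies of early hypo scar, 0.19 and -0.02 in the other 2, and -0.46 to -0.12 in early hyper scar. Lower as well were skeletal muscle genes (-0.83, camera adjusted p = 0.0031, estimated-correlation adjusted p = 0.59). Cytokine and chemokine (-0.29, camera adjusted p = 0.0222, estimated-correlation adjusted p = 0.465) and endothelial genes (-0.22, camera adjusted p = 0.0369, estimated-correlation adjusted p = 0.508) were lower too. The same held for T and NK cell (-0.19, camera adjusted p = 0.0369, estimated-correlation adjusted p = 0.465) and interferon response genes (-0.14, camera adjusted p = 0.0369, estimated-correlation adjusted p = 0.588). Immediate early and heat shock genes (0.45, camera adjusted p = 0.0017, estimated-correlation adjusted p = 0.465) and cell cycle genes (0.16, camera adjusted p = 0.0222, estimated-correlation adjusted p = 0.465) were higher. The mean of the immediate early list was 1.38 in the 49L biopsy of early hyper scar and -0.23 to -0.03 in the other 3. With slide as a fixed block neither of these 2 rises passed (camera adjusted p = 0.0937 and 0.131). No member of these lists passed on its own, also adjusted over the list alone. The 50L biopsy of early hypo scar carried a muscle signal 2.80 log2 units above the median of all arrays.

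In mid scar limma called 0 features as well, with 1763 at an unadjusted p under 0.05. Matrix proteases and inhibitors had lower values in mid hyper scar (-0.67, camera adjusted p = 2.92e-04, estimated-correlation adjusted p = 0.676). Among them were the collagen-degrading cathepsin CTSK (-1.51 ± 0.50), TIMP2 (-0.86 ± 0.30) and TIMP1 (-0.85 ± 0.33), none past the threshold and 0 adjusted over the list alone. Skeletal muscle genes had higher values (1.14, camera adjusted p = 0.0020, estimated-correlation adjusted p = 0.75), with MYOZ1 (1.86 ± 1.21) and CKM (1.63 ± 1.16) not past the threshold. The 49R biopsy of mid pressure hyper scar carried most of that signal. The named genes of lowest p include THY1 (-0.69 ± 0.19), FUT1 (0.50 ± 0.14), CA6 (0.81 ± 0.25) and the cholesterol carrier NPC2 (-1.05 ± 0.33), with adjusted p from 0.517 to 0.517. Leaving out mid pressure hyper replicate 50R gave 101 features, mid sham hyper replicate 49L 8, mid pressure hyper replicate 49R 3, mid sham hyper replicate 50L 3 and mid pressure hypo replicate 50R 2. Animal 49 alone gave 1847.

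In late scar 1005 features differed between hyper and hypo scar, 94 higher and 911 lower in hyper scar, in 4 against 4 arrays of sham and pressure scar together. Most of them, 93.7%, carry no gene symbol. The vessel-related secreted protein ANGPTL1 (1.95 ± 0.52, adjusted p = 0.0342), SIX4 (1.15 ± 0.32, adjusted p = 0.0416) and the hyaluronan-binding protein TNFAIP6 (1.67 ± 0.48, adjusted p = 0.0483) were higher in hyper scar. So were fibrillin FBN1 (1.08 ± 0.29, adjusted p = 0.0346), the sarcoglycan SGCE (0.89 ± 0.24, adjusted p = 0.0383), CYBRD1 (0.90 ± 0.22, adjusted p = 0.0227) and TYR (0.96 ± 0.24, adjusted p = 0.0232). The vitamin D breakdown enzyme CYP24A1 (-1.21 ± 0.25, adjusted p = 0.0115), the interferon receptor chain IFNAR2 (-1.19 ± 0.22, adjusted p = 0.0077), the mucin MUC13 (-1.18 ± 0.25, adjusted p = 0.012) and the deiodinase DIO2 (-1.12 ± 0.28, adjusted p = 0.0288) were lower. The mitochondrial mutase MUT (-1.29 ± 0.24, with 1 of 2 probes in this direction), the caspase CASP10 (-1.21 ± 0.29, 5 of 6 probes), the desaturase-like FADS6 (-1.17 ± 0.33) and the metallothionein MT3 (-1.13 ± 0.26) were lower with adjusted p from 0.0075 to 0.0416. TYR was well above background on 2 of 4 late hyper and 0 of 4 late hypo arrays, in the Cy5 channel at least 1.63-fold higher.

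As lists, matrix genes (0.58, camera adjusted p = 0.0333, estimated-correlation adjusted p = 0.917), matrix proteases and inhibitors (0.54, camera adjusted p = 0.0333, estimated-correlation adjusted p = 0.917) and skeletal muscle genes (1.18, camera adjusted p = 0.0333, estimated-correlation adjusted p = 0.917) were higher in late hyper scar. With slide as a fixed block the muscle list did not pass (camera adjusted p = 0.102). Of these lists 1 matrix gene, FBN1, passed (1 adjusted over the list alone), and 0 of the others. A muscle signal stood 4.78 and 1.67 log2 units above the median of all arrays in 2 of the 4 late hyper biopsies. Late hypo arrays had fewer probes well above background (36.6% against 43.1%). Each of these 15 named calls was lost in at least 1 of 8 fits that left out 1 array, MUT and IFNAR2 in 1 and FBN1 in 8. Without the biopsies with muscle signal 65 features passed, with the Cy5 share as a covariate 23, and without the 2 dimmest arrays 10. The median size of the 1005 differences was then 0.67, 0.65 and 0.75, against 0.80, and the sign was the same in each feature fitted. With backgrounds not capped the count was 169, in the Cy5 channel alone 297, in animal 49 alone 2783 and in animal 50 alone 0. Leaving out 1 array gave 30 without late sham hyper replicate 49L, 125 without late pressure hyper 49R, 239 without late sham hypo 50L, 490 without late pressure hypo 50R and 1550 without late sham hyper 50L. The 1 slide that held both groups had the same direction for 99.4% of the 1005 and 77.8% of all features, but its 3 arrays are among the 8 that gave the calls.

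The difference between hyper and hypo scar was itself larger or smaller in late than in early scar for 946 features, 62 with a higher and 884 with a lower difference. Late scar averages sham and pressure biopsies and early scar is sham alone, so phase is mixed with pressure here. GATA3 (-3.11 ± 0.66, adjusted p = 0.012), CCL27 (-2.75 ± 0.61, adjusted p = 0.015) and the splicing regulator of epithelial cells ESRP1 (-2.70 ± 0.74, adjusted p = 0.0395) had a lower hyper-to-hypo difference in late scar. So did EPCAM (-1.96 ± 0.49, adjusted p = 0.0263), MT1A (-2.97 ± 0.74, adjusted p = 0.0254) and LMO1 (-2.20 ± 0.53, adjusted p = 0.0228). The same held for CYP24A1 (-1.96 ± 0.36, adjusted p = 0.0052) and MUT (-1.87 ± 0.33, with 1 of 2 probes in this direction, adjusted p = 0.0052). Higher in late scar were the differences of ANGPTL1 (2.70 ± 0.74, adjusted p = 0.0396) and the growth factor carriers IGFBP6 (2.39 ± 0.61) and IGFBP2 (2.33 ± 0.67). So were those of the aldehyde dehydrogenase ALDH2 (1.35 ± 0.34, adjusted p = 0.0277), CYBRD1 (1.31 ± 0.31), SGCE (1.24 ± 0.35) and the TNF receptor TNFRSF1B (1.2 ± 0.32, adjusted p = 0.0317). Of these 15 genes GATA3, CYP24A1 and MUT kept their call in each fit that left out 1 array, and IGFBP2 lost it in 13 of 16. Leaving out 1 array gave between 227 (without late sham hyper replicate 49L) and 1670 features (without late sham hyper replicate 50L). The other arrays that moved it most gave 363 to 578. Taken alone, animal 49 gave many calls and animal 50 hardly any, with a single array per late group in each. The sign was the same in both animals for the 914 of the 946 features with values in both. As both animals gave the calls, that is in part built in. With backgrounds not capped 74 passed, in the Cy5 channel alone 69 and without the biopsies with muscle signal 118. Of the fixed lists, macrophage and dendritic cell (1.01, camera adjusted p = 1.07e-04, estimated-correlation adjusted p = 0.777), skeletal muscle (1.75, camera adjusted p = 0.0029, estimated-correlation adjusted p = 0.838) and matrix protease genes (0.76, camera adjusted p = 0.0148, estimated-correlation adjusted p = 0.777) had a higher difference in late scar. In limma 0 of their members passed the threshold, also adjusted over the list alone. Single biopsies carry much of the first 2: the macrophage list had its highest means in 49L of late sham hyper scar (1.42) and in 50L and 49R of early hypo scar (0.97 and 0.63). The muscle list stood 4.78 and 1.67 above the median of all arrays in 49R and 49L of late hyper scar and 2.80 above it in 50L of early hypo scar.

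Hyper and hypo scar over all phases were each set against the same 4 control arrays, so the results of both share the spread of those arrays. In hyper scar 11 of 12 matrix genes rose (12 adjusted over the list alone, median 1.92, camera adjusted p = 4.78e-05, estimated-correlation adjusted p = 0.296). In hypo scar it was 9 of 12 (11 adjusted over the list alone, median 1.96, camera adjusted p = 2.23e-04, estimated-correlation adjusted p = 0.367). ASPN rose by 3.31 ± 0.48 in hyper and 3.25 ± 0.48 in hypo scar, COL5A1 by 2.28 ± 0.39 and 2.31 ± 0.39, and POSTN by 2.27 ± 0.42 and 2.24 ± 0.42. C1QTNF3 rose by 2.65 ± 0.67 and 3.01 ± 0.67, and CRABP1 by 2.19 ± 0.43 and 2.48 ± 0.43. PHEROC fell (-6.61 ± 0.69 and -7.57 ± 0.69), as did SCGB1D1 (-5.79 ± 0.69 and -6.80 ± 0.69), RLN2 (-3.64 ± 0.16 and -3.70 ± 0.16), DAPL1 (-4.02 ± 0.52 and -4.54 ± 0.52) and PLET1 (-3.55 ± 0.40 and -4.91 ± 0.40). These genes had adjusted p from 2.06e-12 to 0.0041 in hyper and adjusted p from 1.64e-12 to 0.0014 in hypo scar. The sebaceous and lipid synthesis list fell in both, 9 of 13 and 9 of 13 genes, the same counts as adjusted over the list alone. These were the 2 of 247 list tests that also passed with an estimated correlation (camera adjusted p = 6.92e-05, estimated-correlation adjusted p = 0.0467 in hyper, camera adjusted p = 1.10e-04, estimated-correlation adjusted p = 0.043 in hypo scar).

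The pigment list was lower than in control skin in both kinds of scar. In hyper scar 6 of 14 pigment genes fell (7 adjusted over the list alone, median -0.46, camera adjusted p = 0.0175, estimated-correlation adjusted p = 0.296). In hypo scar 7 of 14 fell and 1 rose, also adjusted over the list alone (median -0.62, camera adjusted p = 0.0085, estimated-correlation adjusted p = 0.29). TYR fell in hyper (-2.54 ± 0.19) and in hypo scar (-3.38 ± 0.19), as did TYRP1 (-1.30 ± 0.26 and -2.27 ± 0.26), with adjusted p from 1.26e-08 to 6.91e-04 in hyper and adjusted p from 1.42e-10 to 2.60e-06 in hypo scar. In hypo scar TYR and TYRP1 were well above background on 0 of 12 arrays, in the Cy5 channel at least 18-fold and 4-fold lower than in control skin. Endothelial, macrophage, interferon, protease and skeletal muscle lists rose and adipocyte, cell cycle and melanocyte signal lists fell in both kinds, with camera adjusted p from 4.50e-04 to 0.0395 and adjusted p from 0.148 to 0.521 with an estimated correlation in hyper and 4.43e-04 to 0.0436 and adjusted p from 0.276 to 0.709 with an estimated correlation in hypo scar. With slide as a fixed block the adipocyte list did not pass in hyper (camera adjusted p = 0.357) or hypo scar (0.106), nor did the skeletal muscle and melanocyte signal lists in hypo scar (0.0571 each). The muscle signal lay in 3 hyper biopsies, 49R of mid and of late pressure scar and 49L of late sham scar, and in the 50L biopsy of early hypo scar. In all 7135 features passed in hyper scar (4614 higher, 2521 lower) and 7843 in hypo scar (5162 higher, 2681 lower). The direction was the same within slides in 95.8 to 96.8% on 2 slides and 98.6 to 99.5% on 3 slides. Without control replicate 50L 4601 passed in hyper scar, 4549 of them among the 7135. With slide as a fixed block it was 4681, and in animal 50 alone 2622 in hyper and 3783 in hypo scar.

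Pressure-treated scar was compared with sham scar at the mid and late phases to ask what pressure changed. No feature passed in limma (8 against 8 arrays, 957 at an unadjusted p under 0.05). Some fixed lists moved as groups. Smooth muscle and myofibroblast genes had higher values under pressure (0.34, camera adjusted p = 8.19e-04, estimated-correlation adjusted p = 0.458), as did skeletal muscle genes (0.89, camera adjusted p = 2.0e-05, estimated-correlation adjusted p = 0.723). So did matrix (0.32, camera adjusted p = 0.0143, estimated-correlation adjusted p = 0.723) and adipocyte genes (0.07, camera adjusted p = 0.0324, estimated-correlation adjusted p = 0.723). Interferon response genes had lower values (-0.32, camera adjusted p = 6.29e-05, estimated-correlation adjusted p = 0.458), as did macrophage and dendritic cell genes (-0.32, camera adjusted p = 0.0177, estimated-correlation adjusted p = 0.723). So did immediate early and heat shock genes (-0.37, camera adjusted p = 0.0355, estimated-correlation adjusted p = 0.723). The macrophage list stood highest among sham biopsies in 3 of animal 49 (1.42, 1.38 and 0.64, against at most -0.15 in the other 5). With slide as a fixed block the macrophage and adipocyte lists did not pass (camera adjusted p = 0.06 and 0.0669). No member of these lists passed, also adjusted over the list alone. Examples are the calponin CNN1 (0.85 ± 0.28), IFIT1 (-0.51 ± 0.16), the peptide transporter TAP1 (-0.52 ± 0.17) and NFKB1 (-0.33 ± 0.11). The named genes of lowest p also include the kinase inhibitor PKIA (1.17 ± 0.28), the sarcoglycan SGCD (0.75 ± 0.22) and the water channel AQP5 (-0.50 ± 0.16), all 7 with adjusted p from 0.906 to 0.906. Within 5 slides the interferon list lay between -0.86 to 0.07 and the smooth muscle list between -0.18 to 0.82.

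At the mid and late phases pressure was on the right side and sham on the left, so treatment and side go together there. With the right minus left difference of the early sham biopsies subtracted, limma called 0 features, with 303 at an unadjusted p under 0.05. A strong muscle signal lay in 2 pressure biopsies (4.78 and 4.01) and a lesser one in 1 sham biopsy (1.67). In animal 49 alone 1289 features passed, and without late pressure hyper replicate 50R 41.

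The effect of pressure was also compared between hyper and hypo scar. Again no feature passed in limma, with 3482 at an unadjusted p under 0.05. The named genes of lowest p include BTG3 (-1.15 ± 0.21), ARL6IP5 (1.30 ± 0.27), the defensin DEFB1 (-1.07 ± 0.24, with 1 of 2 probes in this direction), LMO4 (-0.88 ± 0.19) and the kinesin KIF21A (-1.57 ± 0.35), with adjusted p from 0.0914 to 0.0914. Macrophage and dendritic cell genes as a list had a higher pressure effect in hyper scar (0.86, camera adjusted p = 0.0378, estimated-correlation adjusted p = 0.966), with CD163 (1.66 ± 0.77) and osteopontin SPP1 (4.21 ± 2.07) not past the threshold and 0 members past it adjusted over the list alone. This list stood high in single biopsies: its mean was 1.29 in the 50R biopsy of mid pressure hyper scar, and 1.42, 1.38 and 0.64 in the 49L biopsies of late sham hyper, mid sham hypo and late sham hypo scar. In the other 12 mid and late biopsies it was 0.18 or lower. The count rested on single biopsies: 1016 features passed without mid pressure hyper replicate 49R, 882 without late sham hyper 49L and 397 without late pressure hyper 50R. Without all 4 biopsies with muscle signal it was 2022.

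**Figure D4:**
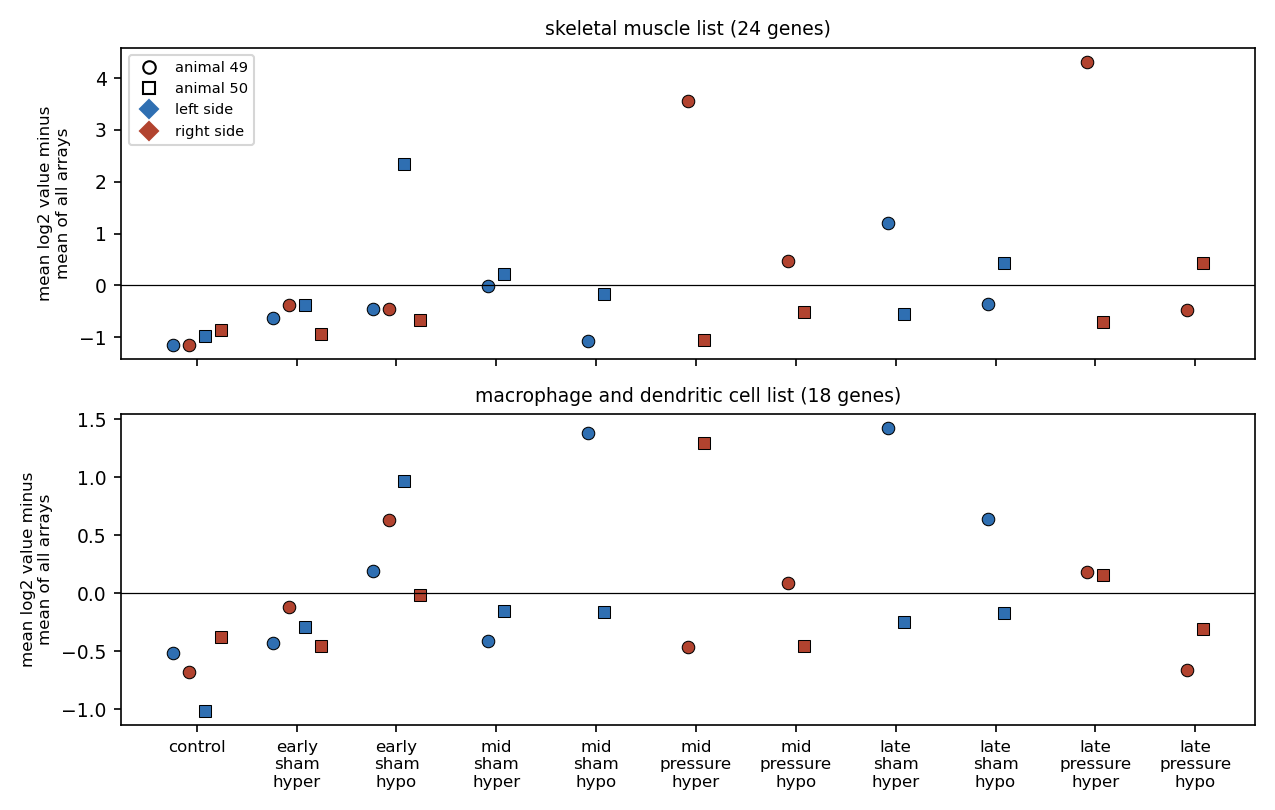
Mean log2 value of the skeletal muscle list (top, 24 genes) and of the macrophage and dendritic cell list (bottom, 18 genes) in each biopsy by group, less the mean of all arrays, with shape for animal and colour for side. The 49R biopsies of late and mid pressure hyper scar lie highest in the muscle list, 4.78 and 4.01 above the median of all arrays.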

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

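Chosen after the results were seen were the fits with the Cy5 share as a covariate, without the muscle biopsies, without the 2 dimmest arrays and with backgrounds not capped, the sizes of the late differences in these fits, the correlation between muscle genes, the differences of gland and pigment genes over pairs, the splits within pairs, and the splits for the late against early difference and for the pressure effect, which replaced a first version that gave 0 for the real split and more for others.

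In 66 checks of a list or another measure within a group of 4 biopsies, 3 found a biopsy far from the other 3. Chance gives about 1 in 20, so this is no more than chance would give. The TGF-beta pathway list (gap over range 0.841) and the immediate early and heat shock list (0.876) set the 49L biopsy of early sham hyper scar apart. The skeletal muscle list (0.93) set the 50L biopsy of early sham hypo scar apart. The difference between hyper and hypo scar changed from early to late scar in 946 features. As lists, the same change was 0.76 for matrix proteases and inhibitors (camera adjusted p = 0.0148, estimated-correlation adjusted p = 0.777), 1.75 for skeletal muscle (camera adjusted p = 0.0029, estimated-correlation adjusted p = 0.838) and 1.01 for macrophage and dendritic cell genes (camera adjusted p = 1.07e-04, estimated-correlation adjusted p = 0.777). The effect of pressure differed between hyper and hypo scar by 0.86 for macrophage and dendritic cell genes (camera adjusted p = 0.0378, estimated-correlation adjusted p = 0.966).

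The number of features that differed between hyper and hypo scar was 1005 in late scar and 0 in early and in mid scar. Each of the 2 technical explanations tested met the condition set for it before the test, since the count fell to 23 with the share of probes well above background as a covariate and to 65 without the biopsies that carried a muscle signal. Among the 1005 features the median difference fell from 0.80 to 0.65 with the covariate (median SE 0.19 and 0.20) and to 0.67 without the muscle biopsies (median SE 0.22), with the sign unchanged in each feature fitted, so the calls ended through smaller differences and, in the latter case, a larger error. Without the 2 dimmest arrays, both late hypo arrays of animal 50, the median difference was 0.75 (median SE 0.24). These arrays helped select the 1005 features, so the kept size decides nothing on their signal. Leaving out the muscle biopsies removed 2 of the 4 late hyper arrays, all those of animal 49, so fewer calls can follow from the loss of arrays or of that animal. The same 2 biopsies also stood high in 7 genes of osteoclasts and activated macrophages described below (mean 3.51 and 1.79). The fall in the count therefore does not point to muscle in particular. Both explanations stay open, as does a difference between late hyper and hypo tissue, which was not tested.

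TYR and TYRP1 were higher in hyper than in hypo scar, on average by 0.90 on the log2 scale, a size that depends on the scaling, with 0.40 and 0.44 where backgrounds were not capped and 2.42 and 4.16 in the scanner program's own ratio. Lower signal of hypo arrays is argued against by the covariate, with which the average was 0.94. A larger share of epidermis in the hyper biopsies was examined with 10 keratinocyte genes. Their median difference, averaged over the 12 pairs of animal, side and phase, was 0.0017 with SE 0.12 (exact two-sided permutation p = 0.987, higher in the hyper biopsy of 5 of 12). As a set these 4 differentiated and 6 activated keratinocyte genes argue against a rise of 0.90. Epithelial EPCAM differed by 0.64 (SE 0.40, exact p = 0.136). A smaller rise stays open, as does a larger basal layer, with 0 genes measured. A larger share of gland epithelium stays open: over the same pairs PLET1 differed by 1.36 (SE 0.37, exact p = 0.0020), PHEROC by 0.95 (SE 0.59, exact p = 0.157) and SCGB1D1 by 1.0 (SE 0.63, exact p = 0.148), while the sebaceous and lipid, sweat gland and hair follicle lists differed by 0.08, 0.16 and 0.12 (SE 0.05, 0.19 and 0.06). More melanin synthesis or more melanocytes stay open too, since no test was fixed for them and the melanocyte genes DCT, KIT and MITF, well above background on 12 of 12 arrays of each kind, differed by 0.17, 0.05 and 0.03.

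Skeletal muscle genes stood 1.67 to 4.78 log2 units above the median of all arrays in 4 scar biopsies. Muscle taken up below the skin is a candidate source that no value here decides: the correlation of 0.74 between the list's genes after the groups were fitted, against at most 0.64 in the other lists, repeats the rise in these biopsies and would follow from any cause of it. The 3 brightest genes, ACTA1, MYLPF and CKM, stood 1.26 to 4.6, 4.27 to 7.47 and 1.65 to 5.89 above their medians in these biopsies. Of the 24 measured genes 20 were well above background in each control biopsy, and 0 belong to another list. No biological explanation was tested.

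Other splits of the same arrays were used to ask whether chance can give as many features, on 16402 features with no missing value. Chance is argued against for early (real 7635, highest other 3290), mid (3721 and 2) and late scar against control skin (5419 and 263), late against early sham scar (3502 and 971), hyper scar (5464 and 14) and hypo scar against control skin (4988 and 2), where 1 of 100 splits, the real one, gave as many. For the late against early difference it was also 1 of 100 (946 and 14). Those splits replaced a first version after its results were seen and were not matched by animal, so no conclusion on chance is drawn there. Of these 946 features 733 are among the 946 called over all features. For late hyper against hypo scar 1 of 35 splits gave as many (440 and 42), which argues against chance, but the 18 splits with the same number of arrays per animal (440 and 0, 1 of 18) are too few for a share under 0.05. For hyper against hypo scar over all phases 1 of 100 splits gave as many (3 and 0), but 3 of 100 with labels swapped within pairs of animal, side and phase (highest other 878). With the pair in the fit of these 24 arrays it was 3 of 100 as well (3 and 1593), a share under 0.05, while splits that call so many point to a structure of the samples beyond pigmentation. With the pair as a block and a separate hyper term for each phase and treatment, on the same 24 arrays, limma called 0 features (335 at an unadjusted p under 0.05). Where the real count was 0 each split gives at least as many, so the splits decide nothing there: early (highest other 5, 35 of 35 splits) and mid hyper against hypo scar (376, 35 of 35), pressure against sham scar (1984, 100 of 100) and the pressure effect (14, 100 of 100). The split that gave 1984 put 3 biopsies with muscle signal on 1 side, which points to a structure of the samples beyond the treatment.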

How the results depend on the processing

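The alternatives with backgrounds not capped, the Cy5 share as a covariate, the muscle biopsies or the 2 dimmest arrays left out and slide as a fixed block were chosen after the data were seen. Of the 15 counts and list values, those not given below stayed on the same side of their threshold or within 1.5 times. No named gene that passed in either fit changed sign. Outside the leave-one-out fits 3404 of 3844 gene values stayed on the same side of the threshold, 406 lost their call, 31 gained one and 3 changed sign without passing in either fit. The cause of a change was not tested, save that an animal alone, left-side biopsies or a left-out array leave fewer arrays. Normalisation between arrays leaves ratios as they are and tests nothing here.

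With the scanner program's ratio 6 features passed between hyper and hypo scar over all phases, 1 in mid scar and 612 in the late against early difference, and the deposited values gave 6, 1 and 618. With the Cy5 channel alone mid scar against control skin gave 4214, late hyper against hypo 297 and the difference 69. With the filter of 14 arrays the pigment list's median in hyper against hypo scar was 0.0372 (adjusted p = 0.663). Animal 49 alone gave 4920 for late scar against control skin, 399, 2, 1847 and 2783 for hyper against hypo scar over all phases, early, mid and late, 2023 for the difference, 1289 for pressure, 1118 for the pressure effect and 0.11 for the pigment list (adjusted p = 0.364). Animal 50 alone gave 2830, 1732 and 4554 for early, mid and late scar against control skin, 1052 for late against early sham scar, 2 and 0 for mid and late hyper against hypo scar, 1 for the difference, 2622 and 3783 for hyper and hypo scar against control skin and 6 for the pressure effect. The pair of animal, side and phase as a block gave 0, 589 and 516 for hyper against hypo scar over all phases, late and the difference. Left-side biopsies alone gave 264 for late against early sham scar. With an estimated correlation 2 of 83 list tests passed, and the pigment list (median 0.0569) did not (adjusted p = 0.408).

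With backgrounds not capped, late against early sham scar gave 11, hyper against hypo scar 0 over all phases and 169 in late scar, the difference 74 and the pigment list 0.0595 (adjusted p = 0.138). With the covariate late scar against control skin gave 3359, late against early sham scar 758, late hyper against hypo 23 and the difference 251. Without the muscle biopsies hyper against hypo scar gave 5 over all phases, 3 in mid and 65 in late scar, the difference 118, pressure 1 and the pressure effect 2022. Without the 2 dimmest arrays late against early sham scar gave 2420, hyper against hypo 1 over all phases and 10 in late scar, the difference 430 and pressure 4. Slide as a fixed block gave 3806 for mid scar, 980 for late against early sham scar, 0 and 34 for hyper against hypo scar over all phases and mid, 427 for the difference, 4681 for hyper scar against control skin and 399 for the pressure effect.

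Leaving out 1 array gave 5464 to 7331 for early, 3899 to 6601 for mid and 5371 to 7671 for late scar against control skin, 4601 to 7465 for hyper and 5416 to 8067 for hypo scar against control skin, 2119 to 3704 for late against early sham scar, 1 to 8, 0 to 2, 0 to 101 and 30 to 1550 for hyper against hypo scar over all phases, early, mid and late, 227 to 1670 for the difference, 0 to 41 for pressure, 0 to 1016 for the pressure effect, 73 to 88 lists and a pigment list median of 0.0122 to 0.13. Without late pressure hyper replicate 50R the pigment list missed the threshold (0.08, adjusted p = 0.0886). Without control replicate 50L mid scar gave 3899 and hyper scar 4601. Over all phases 8, 7 and 5 features passed without mid sham hyper 49L, late sham hyper 49L and late pressure hypo 49R, and 1 each without late sham hyper 50L, late sham hypo 49L and late pressure hypo 50R. Where 1 array of a group was left, it was assumed to vary like the other groups. Of 198 named gene calls 45 were lost without some array, 9 of them without 1 array alone.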

Other observations

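All values in this part were picked after they were seen, and no test was run beyond the fit that gave the adjusted p values (limma). Among genes outside the lists that passed as a group, early scar had lower levels of the cortisol-activating enzyme HSD11B1 (-1.96 ± 0.18, adjusted p = 2.71e-07) and the oestrogen sulfotransferase SULT1E1 (-2.16 ± 0.27, adjusted p = 5.00e-06), and a higher level of the retinoic acid binding protein CRABP1 (2.98 ± 0.46, adjusted p = 4.69e-05) than control skin. The early response genes moved apart, with MYC (-1.15 ± 0.19, adjusted p = 7.81e-05) lower and JUN (1.67 ± 0.32, adjusted p = 3.85e-04) higher. The antimicrobial peptide PMAP-23 (-1.62 ± 0.18, adjusted p = 1.41e-06) was well above background on 0 of 8 early scar and 4 of 4 control arrays, in the Cy5 channel at least 2.73-fold lower.

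In 7 scar biopsies 6 genes known from osteoclasts and activated macrophages stood high together: osteopontin SPP1, the acid phosphatase ACP5, the fusion receptor DCSTAMP, the elastase MMP12, CLEC5A and MMP9. The cathepsin CTSK did not follow them, at 0.26 to 1.71 above the mean of all arrays in these biopsies and up to 1.73 in others. The mean deviation of all 7 genes was 3.51 in late sham hyper 49L, 3.47 in mid sham hypo 49L, 3.04 in mid pressure hyper 50R and 2.70 in early sham hypo 50L. It was 2.43 in late sham hypo 49L, 2.05 in early sham hypo 49R and 1.79 in late pressure hyper 49R. In the other 21 biopsies it was -0.08 or lower, and in the 4 control biopsies -1.18 to -1.04. The 7 biopsies come from 6 groups and both animals.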
